A study of Acinetobacter baumannii with 18 samples.

How the data were processed

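Transcripts of Acinetobacter baumannii were measured by RNA sequencing in 18 libraries, 3 for each of 6 conditions (control, colistin, colistin B, polymyxin B, sulbactam, colistin with sulbactam), all at 4 h per the labels. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a SMARTer mRNA-Seq kit from total RNA. Per the submitters' processing notes, cutadapt, which trims adapters, and Bowtie2, a read aligner, were used, with no versions given. The genome build, the annotation, the program that counted reads, the handling of reads that map to several places and the use of strand are not given in the sources used here. Reads of near-identical genes, overlapping genes and antisense partners may therefore be shared between their counts.

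The authors' deposited table holds raw read counts per gene, whole numbers that are not normalised, for 3630 genes in each library. It also holds FPKM values that the authors computed and deposited beside the counts. Each FPKM value equalled the count scaled by gene length and by the total count of its library, within a relative tolerance of 1e-09 for 100% of the values, so the FPKM values add nothing to the counts and were not tested. The gene lengths are multiples of 3 for 99.5% of genes and are called coding lengths here (75 to 10359 nt, median 795). The table names genes by locus tag only. None of the 3630 tags (0 matches) was found in the table of names used here, which describes another strain with 3901 genes. No gene name was inferred from a tag, its place or its length. The 35 gene lists fixed before the data were examined, the set tests on them, the panel of resistance genes and the part of the rule for named genes that needs a symbol therefore could not be used. The rule was narrowed once the tags were found to have no names, and names the 2 genes with the largest mean rise and the 2 with the deepest mean fall over the 3 polymyxins, among genes called in all 3, with a mean of at least 10 CPM over all libraries and with libraries of each drug that do not overlap those of control. Any other gene or run of genes named was chosen after its values were seen, and the text says so where it appears. Groups of genes are defined by their calls.

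Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with low counts were left out with filterByExpr (minimum count 10, minimum total 15), which kept 3508 genes and removed 122. Libraries were scaled by TMM, with factors of 0.947 ± 0.00752 in control and 1.07 ± 0.0180 in the combination (SD, n = 3). All 18 libraries entered a single quasi-likelihood fit with 1 mean per condition, which leaves 12 residual degrees of freedom. Its 10 pairwise contrasts and the difference of differences of colistin and sulbactam were tested (glmQLFTest). A gene was called when its Benjamini-Hochberg adjusted p was under 0.05, with no minimum fold. Standard errors were taken as the log2 fold change over the square root of its F value, and 95% confidence intervals from the same fit. Levels are CPM after TMM scaling, given as mean ± SD of 3 libraries. All values are relative to the other transcripts of a library, so a change in the total RNA of a cell cannot be seen.

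Depth was similar between libraries (9023102 to 12173720 reads), and the median standard error of a log2 fold change between 2 conditions was close to 0.118, against 0.167 for the difference of differences. Tested on simulated counts for colistin against control over 3508 genes, the procedure recovered 22% of genes changed 1.25-fold, 84% at 1.5-fold, 96% at 2-fold and 100% at 4-fold (50 genes each). It called 8 of 3308 unchanged genes, and 0 genes when nothing was changed. The replicates were compared before they were averaged. The chi-square per degree of freedom of the 18 replicate pairs ran from 6.52 to 95.8 over genes with at least 20 reads, so no pair agreed within sampling noise. The pairs of colistin B replicate 1, polymyxin B replicate 1 and sulbactam replicate 2 were the most distant in their groups.

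The overlap of responses to the polymyxins was set against 50 simulations of unchanged groups that share the 3 control libraries. The splits of libraries for the difference of differences were also run with the additive effects of colistin and sulbactam, fitted on the 12 libraries of these groups, held as offsets, after a check on simulated counts. Responses per library were compared by exact permutation over the 20 assignments of 3 against 3. Correlations between comparisons that share no library were computed across genes. Neighbouring genes were taken as locus tags whose numbers differ by 5, the step of the numbering, and tested against 1000 shuffles of the genes, after a check on simulated values. The numbering follows an annotation that was not used here, and where a replicon or contig ends is not known. Alternatives tried were DESeq2 1.42.0, RLE scaling, no filter on low counts, a fit of the compared groups only, a replicate block, a minimum fold of 2, each library left out in turn, and, added after the data were seen, the 3 most distant libraries left out together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.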

Results

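RNA of Acinetobacter baumannii, a Gram-negative hospital pathogen, was sequenced after 4 h in 6 conditions with 3 replicates each, 18 libraries in all. The series title describes the organism as carbapenem-resistant and names the question as how polymyxins, and colistin together with sulbactam, act on it. The conditions were an untreated control, colistin, colistin B, polymyxin B, sulbactam, and colistin combined with sulbactam. Polymyxins are cationic lipopeptide antibiotics that bind lipid A in the outer membrane. Sulbactam is a beta-lactamase inhibitor that also binds penicillin-binding proteins of this genus. The sources used here give no dose for any drug. The libraries held between 9023102 and 12173720 reads assigned to 3630 genes, and the largest was 1.35 times the smallest. After genes with low counts were left out, 3508 genes were tested. The genes carry locus tags without names, so gene groups are described below by how they responded, and single genes by locus tag and coding length. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

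The conditions separated widely. The first principal component of the log2 expression values held 66.7% of the variance and the second held 13.6%. On the first component the control libraries lay between -32.7 and -30.5 and the sulbactam libraries between -30.0 and -28.5. Colistin B lay between -3.93 and 0.693, colistin between 11.3 and 11.8, polymyxin B between 18.3 and 25.5, and the combination between 27.7 and 29.9. The gene with the most reads over all libraries, HPJ52_RS18300 (coding length 222 nt), took 4.93% ± 0.0384 (SD, n = 3) of all reads in control. That share was 1.47% ± 0.128 with colistin, 1.46% ± 0.265 with polymyxin B and 0.413% ± 0.0749 with the combination (n = 3 each). It was 2.28% ± 1.03 with colistin B and 4.32% ± 1.37 with sulbactam, groups in which the replicates differed most. This gene was singled out after its values were seen.

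**Figure D1:**
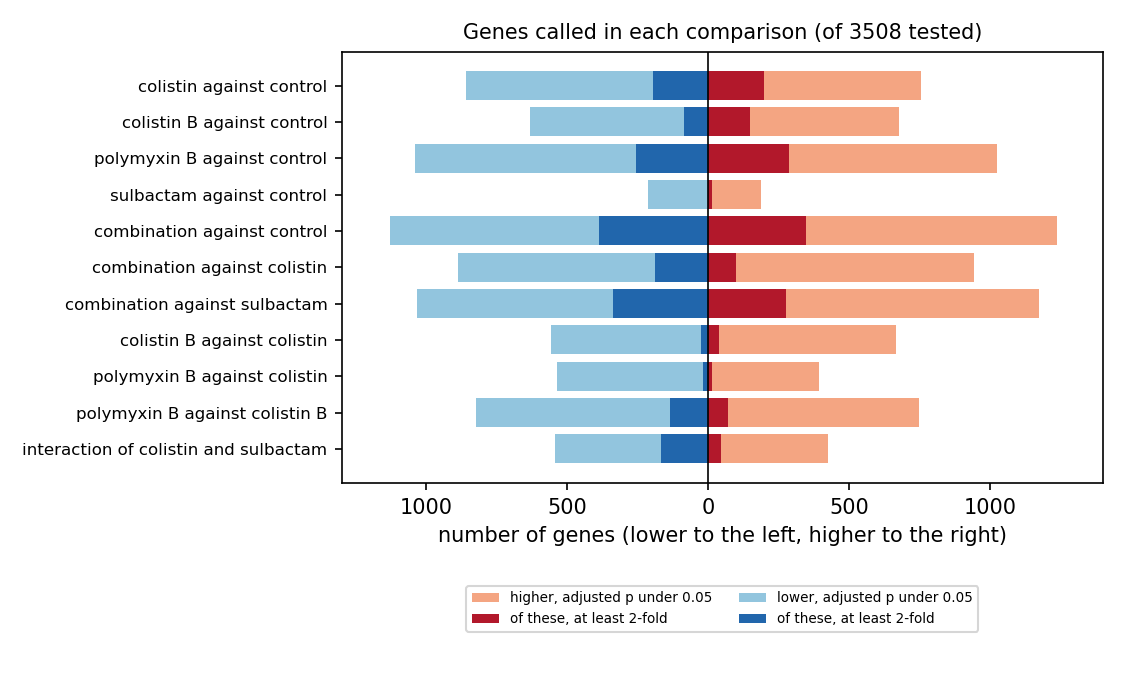
Number of genes called higher (right) or lower (left) in each of the 11 comparisons at an edgeR adjusted p under 0.05, with darker bars for those changed at least 2-fold, among 3508 tested genes. Sulbactam alone changed 402 genes and the combination changed 2369, both against control.

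Colistin against control asked what this polymyxin changes on its own. Colistin raised 755 genes and lowered 859, and 200 and 196 of these changed at least 2-fold. The largest rise was in HPJ52_RS05270 (321 nt), from 11.1 ± 5.07 normalised read counts (CPM) in control to 5808 ± 459 with colistin (SD, n = 3). Its log2 fold change was 9.04 (SE 0.267, edgeR adjusted p = 1.57e-16). HPJ52_RS12110 (384 nt) rose from 10.8 ± 2.99 to 4932 ± 153 CPM, a log2 fold change of 8.84 (SE 0.265). The deepest falls were in HPJ52_RS18315 (429 nt), from 299 ± 46.0 to 6.38 ± 0.964 CPM, and HPJ52_RS16720 (471 nt), from 503 ± 58.0 to 11.7 ± 0.675 CPM. Their log2 fold changes were -5.55 (SE 0.281, edgeR adjusted p = 1.04e-12) and -5.43 (SE 0.182, edgeR adjusted p = 1.03e-15).

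Colistin B, a component of colistin that differs from the main one in its fatty acyl chain, raised 679 genes and lowered 632, or 607 and 723 with RLE scaling. At least 2-fold changes were seen in 148 genes that rose and 85 that fell. HPJ52_RS05270 reached 4878 ± 547 CPM (log2 fold change 8.79, SE 0.265) and HPJ52_RS12110 reached 3036 ± 477 CPM (8.14, SE 0.259). HPJ52_RS18315 fell to 42.7 ± 2.25 CPM and HPJ52_RS16720 to 78.2 ± 22.4 CPM. Their log2 fold changes were -2.81 (SE 0.231) and -2.69 (SE 0.153), with edgeR adjusted p values of 4.22e-09 and 1.15e-11.

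Polymyxin B, which differs from colistin in a single amino acid of its peptide ring, raised 1027 genes and lowered 1042. Of these, 286 rose and 257 fell at least 2-fold. HPJ52_RS05270 stood at 6139 ± 158 CPM (log2 fold change 9.12, SE 0.268) and HPJ52_RS12110 at 5070 ± 288 CPM (8.88, SE 0.265). HPJ52_RS18315 fell to 6.12 ± 4.44 CPM (-5.60, SE 0.281) and HPJ52_RS16720 to 9.22 ± 1.97 CPM (-5.76, SE 0.186).

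The polymyxins changed a large common group of genes. Colistin, colistin B and polymyxin B all raised 427 genes and all lowered 422, so that 849 of the 2508 genes called with at least 1 of them were called in the same direction with all 3. Within this group 130 genes rose and 73 fell at least 2-fold with each of the 3 drugs. Calls in opposite directions between polymyxins were found in 52 genes. Colistin and polymyxin B shared 1349 calls in the same direction (637 up and 712 down, where independent lists would share 221 and 255). Colistin and colistin B shared 922 (expected 146 up and 155 down), and colistin B and polymyxin B shared 1012 (expected 199 up and 188 down). Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.926 for colistin and polymyxin B, 0.866 for colistin and colistin B, and 0.841 for colistin B and polymyxin B. All 3 drugs were compared with the same control libraries, and simulated groups with no effect gave mean correlations of 0.501, 0.491 and 0.495 against those controls. The covariances were 0.681, 0.429 and 0.491, where the simulated ones were 0.0145, 0.0144 and 0.0144. The 3 controls are too few to split, so part of the excess in shared calls may come from them.

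**Figure D2:**
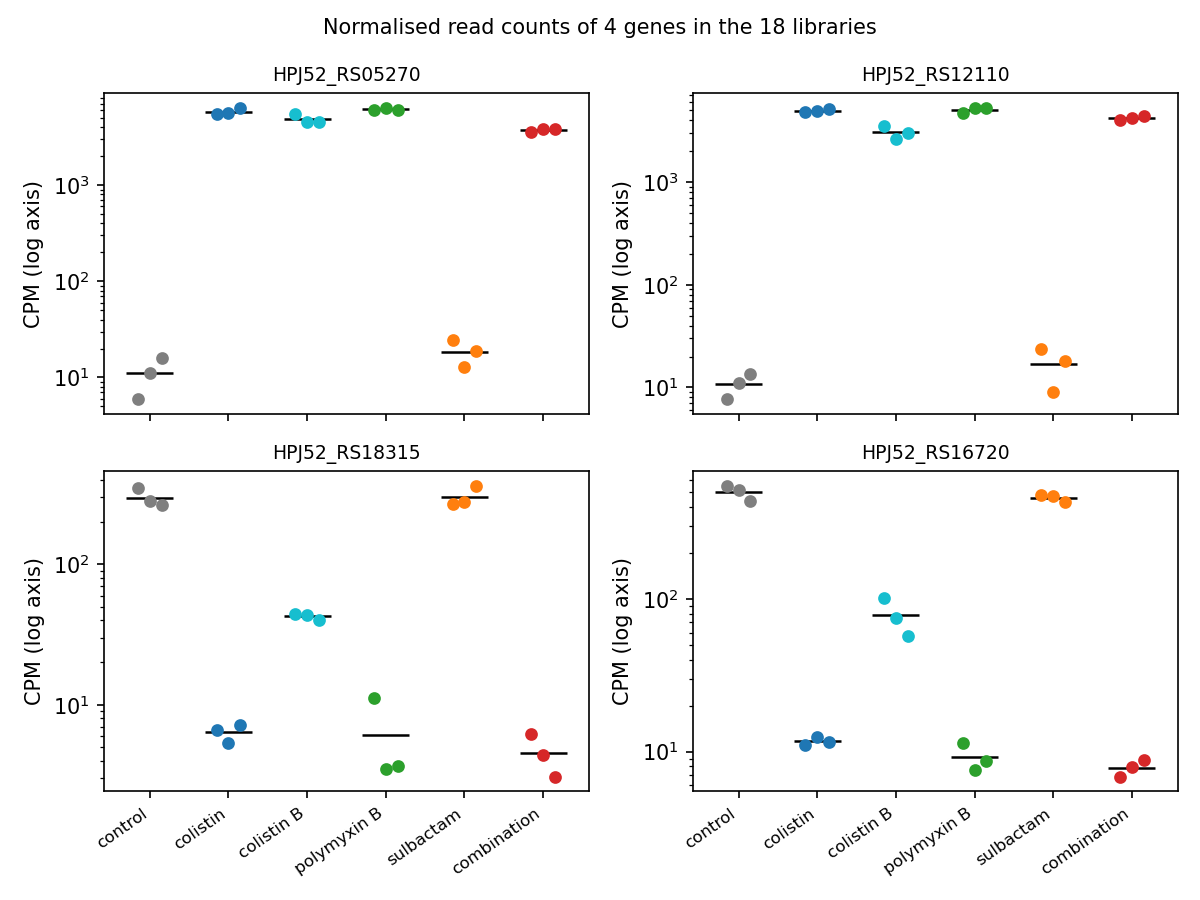
Normalised read counts (CPM) on a log axis for 2 genes that rose (top) and 2 that fell (bottom) in each of the 18 libraries, one point per library, with the mean of the 3 replicates as a line. HPJ52_RS05270 stood at 11.1 CPM in control and 5808 with colistin, and HPJ52_RS18315 at 299 and 6.38.

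Polymyxin B and colistin B were then set against colistin. The labels give all 3 the same time point, and the doses are not in the sources used here. Colistin B differed from colistin in 1225 genes (666 higher and 559 lower), 63 of them at least 2-fold. With RLE scaling 533 were higher and 660 lower. HPJ52_RS18315 and HPJ52_RS16720 were both higher with colistin B than with colistin by 2.74 on the log2 scale (95% confidence intervals 2.16 to 3.33 and 2.38 to 3.10; edgeR adjusted p = 6.68e-07 and 4.20e-09). HPJ52_RS12110 was lower with colistin B by -0.70 (interval -1.08 to -0.32, edgeR adjusted p = 0.00587). HPJ52_RS05270 did not pass the test (-0.25, interval -0.63 to 0.13).

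Polymyxin B differed from colistin in 932 genes (395 higher and 537 lower), 34 of them at least 2-fold. None of the 4 named genes passed the test here, and their intervals were -0.30 to 0.46 for HPJ52_RS05270, -0.34 to 0.42 for HPJ52_RS12110, -0.75 to 0.65 for HPJ52_RS18315 and -0.75 to 0.08 for HPJ52_RS16720. Without polymyxin B replicate 1, HPJ52_RS18315 was lower with polymyxin B by -0.84 (edgeR adjusted p = 0.0300), and without the 3 libraries farthest from their groups so was HPJ52_RS16720, by -0.52 (edgeR adjusted p = 0.0280). Leaving out polymyxin B replicate 3 brought the count down to 620, and leaving out each of the other libraries of these groups in turn gave at most 975. The 34 genes became 20 without polymyxin B replicate 3, 61 without polymyxin B replicate 1 and 53 without colistin replicate 3, and also 61 without the 3 libraries farthest from their groups. Polymyxin B differed from colistin B in 1572 genes (748 higher and 824 lower, or 841 and 760 with RLE scaling), 204 of them at least 2-fold. HPJ52_RS18315 was lower with polymyxin B than with colistin B by -2.79 (interval -3.38 to -2.21) and HPJ52_RS16720 by -3.08 (interval -3.45 to -2.71). Of the genes that did not pass the test, the 95% interval of the difference lay within 2-fold for 92.9% (colistin B against colistin), 93.2% (polymyxin B against colistin) and 92.3% (polymyxin B against colistin B).

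To compare the size of the responses, a set of genes was taken from libraries that enter none of the polymyxin groups or the control. It held the 613 genes that differed at least 2-fold between the combination and sulbactam alone, 275 higher and 338 lower. Colistin moved 522 of them in the same direction against control and 2 in the opposite one. Colistin B moved 406 in the same direction and 13 in the opposite one, and polymyxin B moved 575 in the same direction. Sulbactam, whose own libraries define the set, moved 60 and 40. The mean signed log2 difference from control over the set was 0.832 ± 0.0849 with colistin B, 1.26 ± 0.0232 with colistin and 1.61 ± 0.123 with polymyxin B (SD, n = 3). It was 0.0307 ± 0.0174 with sulbactam and 1.96 ± 0.0458 with the combination, the groups that define the set. The value for sulbactam was 0.00811 without control replicate 1, 0.00878 without sulbactam replicate 1 and 0.0127 without sulbactam replicate 2. The 3 libraries of each polymyxin did not overlap with those of another. The exact two-sided permutation p was 0.1 for each pair of polymyxins, the smallest that 3 against 3 libraries allow, and 0.117 after adjustment over 7 tests. Gene by gene, 348 members moved less with colistin B than with colistin and 18 moved further. With polymyxin B, 287 moved further than with colistin and 10 moved less. Polymyxin B against colistin B gave 489 members that moved further and 5 that moved less.

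**Figure D3:**
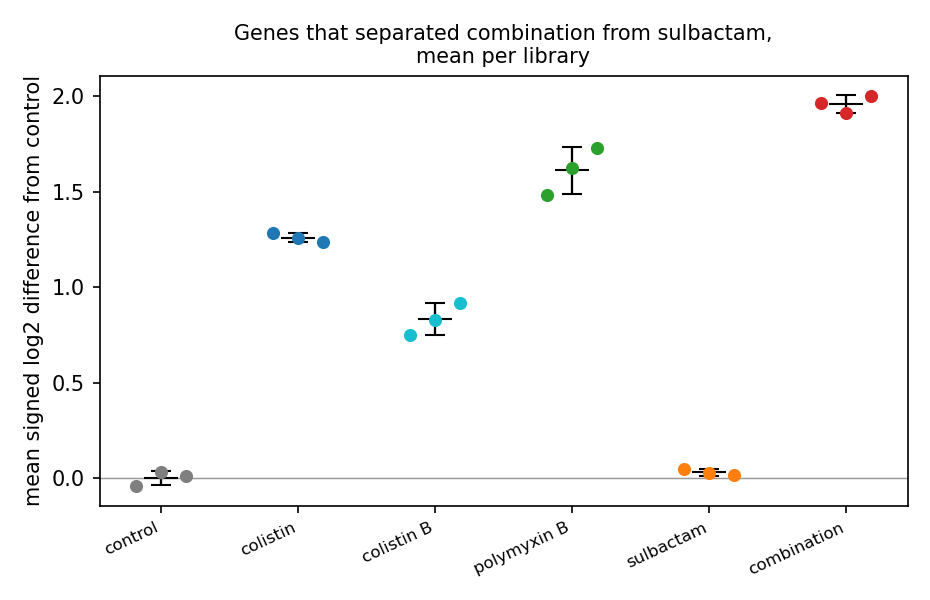
Mean signed log2 difference from the control mean over the 613 genes that separated the combination from sulbactam, one point per library, with the mean and SD of the 3 replicates of each condition. The values lie near 0.832 for colistin B, 1.26 for colistin, 1.61 for polymyxin B and 1.96 for the combination, and sulbactam lies at 0.0307.

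Sulbactam alone changed few genes, and by little. It raised 188 genes and lowered 214, and 12 and 2 of these changed at least 2-fold. Without sulbactam replicate 3, the 14 genes changed at least 2-fold became 9, all of them higher. The 2 genes that fell at least 2-fold, named after their values were seen, were HPJ52_RS02410 and HPJ52_RS08305. HPJ52_RS02410 (591 nt) went from 27.5 ± 1.64 to 13.6 ± 0.866 CPM (log2 fold change -1.02, edgeR adjusted p = 1.05e-04) and stood at 13.4 ± 0.764 CPM with the combination. HPJ52_RS08305 (303 nt) went from 4.29 ± 0.572 to 2.09 ± 0.791 CPM (-1.04, edgeR adjusted p = 0.0401), a call lost without control replicate 1 or 2 or without sulbactam replicate 2 or 3, at values of -0.998 to -0.868 (edgeR adjusted p 0.109 to 0.151). None of the 4 genes named for the polymyxins passed the test. Their log2 fold changes were 0.74 for HPJ52_RS05270 (edgeR adjusted p = 0.0507), 0.64 for HPJ52_RS12110 (0.0987), 0.02 for HPJ52_RS18315 and -0.13 for HPJ52_RS16720. HPJ52_RS05270 passed the test with RLE scaling (edgeR adjusted p = 0.0493) and, like HPJ52_RS12110, without control replicate 3 or sulbactam replicate 2. The standard deviation of log2 fold changes over all genes was 0.283 with sulbactam, against 0.791 with colistin, 0.627 with colistin B and 0.930 with polymyxin B. The count of 402 genes fell to 203 without control replicate 2, to 215 without control replicate 1 and to 246 without sulbactam replicate 3, and was 430 without control replicate 3. More genes were higher than lower without sulbactam replicate 1 (160 and 126) or sulbactam replicate 2 (162 and 153).

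Colistin with sulbactam raised 1238 genes and lowered 1131 against control, of which 349 and 388 changed at least 2-fold. With RLE scaling the counts were 1179 and 1181. HPJ52_RS05270 stood at 3758 ± 164 CPM (log2 fold change 8.41, SE 0.261) and HPJ52_RS12110 at 4204 ± 201 CPM (8.61, SE 0.263). HPJ52_RS18315 fell to 4.56 ± 1.57 CPM (-6.02, SE 0.293) and HPJ52_RS16720 to 7.85 ± 0.991 CPM (-6.00, SE 0.190). Of the 849 genes that all 3 polymyxins changed in the same direction, 780 (91.9%) were called in that direction with the combination and 12 in the opposite one, all against the same control libraries. With sulbactam alone, 129 of the 849 were called in the same direction and 39 in the opposite one. Of the genes that sulbactam raised, 133 were higher and 36 lower with the combination than in control. Of those it lowered, 168 were lower and 20 higher. Independent lists would share 66.3 genes that rose and 69.0 that fell, and part of the excess may come from the shared controls. Simulated unchanged groups shared 0 calls in 50 simulations, but groups with no effect give few calls to share, so this decides nothing. The libraries of colistin and control are separate from those of the combination and sulbactam. Between these separate comparisons, the log2 fold changes of the combination against sulbactam correlated across genes with those of colistin against control at r = 0.837, with 1265 calls in the same direction and 69 in the opposite one. The correlation was higher with polymyxin B against control (r = 0.907, 1625 and 43 calls). It was lower with colistin B against control (r = 0.705, 866 and 135 calls). The likeness to colistin is therefore not particular to that drug.

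The combination differed from colistin alone in 1832 genes, 945 higher and 887 lower (826 and 969 with RLE scaling), of which 98 and 189 differed at least 2-fold. HPJ52_RS18300, the gene with the most reads over all libraries, was lower with the combination than with colistin by -2.01 on the log2 scale (SE 0.262, edgeR adjusted p = 2.69e-06). HPJ52_RS05270 was also lower, by -0.63 (SE 0.182, edgeR adjusted p = 0.00688), and HPJ52_RS12110 did not pass the test (-0.23, SE 0.181) except when the libraries of these conditions were fitted alone (-0.25, edgeR adjusted p = 0.00529). HPJ52_RS16720 was lower by -0.58 (SE 0.207, edgeR adjusted p = 0.0252), a call lost without colistin replicate 2 or 3 or without replicate 1 or 2 of the combination, at values of -0.58 to -0.48 (edgeR adjusted p 0.0524 to 0.0988). Against sulbactam alone, the combination changed 2205 genes, 1173 higher and 1032 lower, or 1088 and 1096 with RLE scaling.

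The difference of differences tests on the log2 scale whether sulbactam changed a gene by the same amount with and without colistin. It passed for 971 genes, 426 above and 545 below the sum of the single drugs, and 44 and 169 of these differed at least 2-fold. The majority below the sum turned with no filter on low counts (547 above and 483 below), without control replicate 1 (484 and 472) and without colistin replicate 2 (466 and 448). It widened with RLE scaling (339 and 591), DESeq2 (371 and 627) and a fit of the 4 groups only (370 and 694). Of the 169 genes at least 2-fold below that sum, colistin alone lowered 108 and raised 31. Of the 971, 803 were not called with sulbactam alone, which called only 402 of the 3508 tested genes (11.5%), so most genes were not called with it in any case. HPJ52_RS18300 lay below the sum by -1.77 (SE 0.360, edgeR adjusted p = 0.000975). HPJ52_RS05270 lay below it by -1.37 (SE 0.301, edgeR adjusted p = 0.00193). HPJ52_RS12110 lay below it by -0.87 (SE 0.303, edgeR adjusted p = 0.0379), a call that was lost without any 1 of the 12 libraries except control replicate 3 or sulbactam replicate 2. Where it was lost, its value was -0.54 without sulbactam replicate 1, -0.62 without control replicate 1 and between -0.90 and -0.80 otherwise. HPJ52_RS18315 (-0.49, interval -1.36 to 0.37) and HPJ52_RS16720 (-0.44, interval -0.97 to 0.08) did not pass the test, although HPJ52_RS16720 did when only the 4 groups involved were fitted (-0.51, edgeR adjusted p = 0.0235).

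The combination against colistin was also set, over all 3508 tested genes, beside comparisons that share no library with it. Its log2 fold changes correlated across genes at r = 0.571 (Spearman's rho 0.545) with those of polymyxin B against colistin B, and 912 genes were called in the same direction in both, where independent lists would share 410, against 111 in opposite directions. With sulbactam against control the correlation was r = 0.337 (rho 0.379), with 266 genes called in the same direction and 44 in opposite ones, where 105 each would be shared by independent lists. Genes are not independent replicates, so no p-value is attached to these correlations.

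**Figure D4:**
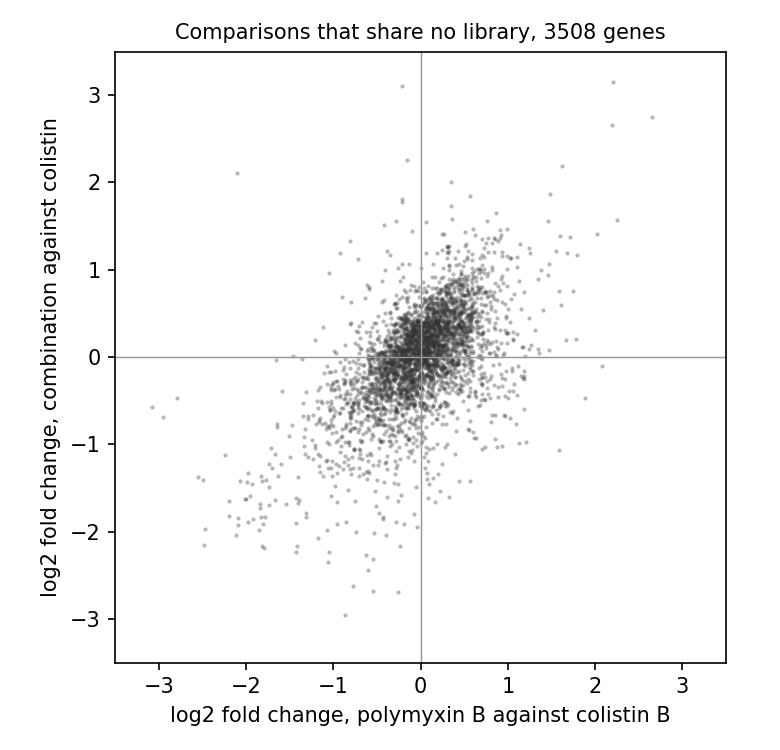
Log2 fold change of the combination against colistin (vertical) plotted over that of polymyxin B against colistin B (horizontal), one point for each of 3508 genes. The comparisons share no library, and the points follow a rising trend with r = 0.571 across genes.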

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

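The redrawing of sulbactam labels and the splits with offsets were chosen after the other splits had been seen, and the correlation with polymyxin B against colistin B was known before its bound was set. Sulbactam's effect differed with and without colistin in 971 genes by the test of the difference itself. Among the named genes, the difference was -1.77 on the log2 scale for HPJ52_RS18300, -1.37 for HPJ52_RS05270 and -0.87 for HPJ52_RS12110, the last close to the threshold. Of the 12 libraries left out in turn, its call was kept without control replicate 3 (-1.04) or sulbactam replicate 2 (-1.18). It was lost without sulbactam replicate 1 (-0.54) or control replicate 1 (-0.62), and without any of the 8 others at values of -0.90 to -0.80 (edgeR adjusted p 0.0557 to 0.0803). With colistin alone HPJ52_RS18300 fell, and it fell further with the combination, while HPJ52_RS05270 rose, and it rose less with the combination. The -1.37 of HPJ52_RS05270 is -0.63 between the combination and colistin less 0.74 with sulbactam alone. That 0.74 was not called, between 11.1 ± 5.07 CPM in control and 18.6 ± 5.76 with sulbactam. For HPJ52_RS12110 the parts were -0.23 and 0.64, neither called. HPJ52_RS05270 kept its call with each of the 12 libraries left out in turn, at -1.71 to -1.01.

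The tables argue against a few abundant genes as the source, since 92.4% of the calls outside the 20 genes with the most reads were kept when those genes were left out (888 of 961). They also argue against unequal depth, since 95.1% of the calls were kept after all libraries were thinned to the smallest total (923 of 971). What stays open is that the combination may lie further along the polymyxin response than colistin alone. Of the 971 genes, 240 that colistin lowered lay below the sum and 116 that it raised lay above it. Against that direction, 145 that colistin raised lay below the sum and 80 that it lowered lay above it. The other 390 were not called with colistin. Only part of the genes thus went along the colistin response. The colistin and control libraries enter both the difference and these calls, with opposite signs. Noise in them alone would move genes against that direction, so these counts cannot decide the question. Across all tested genes the differences correlated at r = 0.530 with polymyxin B against colistin B, a comparison of other libraries. Of the genes called in both, 556 went in the same direction and 68 in opposite ones. The correlation across all tested genes accounts for 28.1% of the variance of the differences. Across the 971 called genes alone it was r = 0.694, but these genes were chosen by the test of that difference. The combination against colistin followed colistin B against control only weakly (r = 0.149). Whether the colistin dose was equal with and without sulbactam is not known from the labels, and no other biological explanation was tested.

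Among 100 splits of the 12 libraries, the real one included, 5 gave as many as 971 genes, with 1276 in the highest other. The 4 others all placed the libraries with colistin unevenly on the plus and minus sides of the difference: splits with 5 of the 6 on 1 side (4 splits) gave 864 to 1276 genes, 3 of the 54 with 4 on 1 side gave any, and the 41 with 3 on each side gave 0 in the highest case. When sulbactam labels were redrawn within the 6 libraries with colistin and the 6 without it, 6 of 50 splits gave as many, with 1668 in the highest other. The 5 others all kept the combination apart from colistin, and the remaining 44 gave at most 2 genes. Taken alone these counts do not exclude chance, but they also pick up the separate effects of colistin and sulbactam. With those effects held as offsets, the real split was the only 1 of the same 100 to give as many (highest other 301) and the only 1 of the same 50 (highest other 141). The 4 splits that had given as many then gave 0 genes, and 5 others gave any. This argues against chance only as spread between single libraries. The offsets were fitted on the same 12 libraries with their real labels and leave the real count at 971. A difference particular to the libraries of 1 condition, such as a shared culture, would give the same outcome.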

How the results depend on the processing

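Of the alternatives to the counts of called genes, the leaving out of 3 distant libraries was chosen after the data were seen, as were those for the response over 613 genes. The counts stayed within 1.5 times the reported ones for all 11 comparisons with DESeq2, RLE scaling, no filter on low counts, only the compared groups and the replicate block, and for the 8 comparisons that involve the 3 distant libraries when these were left out, although the 34 genes changed at least 2-fold between polymyxin B and colistin then became 61. DESeq2 called again between 91.3% and 99.8% of the genes, and RLE scaling between 89.1% and 99.4%. RLE scaling turned the majority for colistin B against colistin from 666 higher and 559 lower to 533 and 660, for the combination against colistin from 945 and 887 to 826 and 969, against sulbactam to 1088 and 1096 and against control to 1179 and 1181, for colistin B against control to 607 and 723 and for polymyxin B against colistin B to 841 and 760. DESeq2 turned all of these except the combination against sulbactam, so these majorities rest on the scaling. A minimum fold of 2, which by its construction leaves fewer genes, left 396 genes for colistin, 233 for colistin B, 543 for polymyxin B, 14 for sulbactam and 737 for the combination against control. It left 287 for the combination against colistin, 613 against sulbactam, 63 for colistin B against colistin, 34 for polymyxin B against colistin, 204 for polymyxin B against colistin B and 213 for the difference of differences. With 1 library left out, sulbactam against control ranged from 203 (without control replicate 2) to 430 (without control replicate 3), with 215 without control replicate 1 and 246 without sulbactam replicate 3, and polymyxin B against colistin from 620 (without polymyxin B replicate 3) to 975 (without polymyxin B replicate 2). Fewer libraries were fitted there, and beyond that the cause was not tested. The other 9 comparisons stayed within 1.5 times. Replicate numbers did not pair the samples throughout: same-numbered samples correlated in their deviations between -0.234 and 0.432 (median 0.0603 over 45 pairs). In 0 of 10 comparisons did every sample fit its own number best. Between polymyxin B and colistin B the values for replicates 1, 2 and 3 were 0.432, 0.0938 and 0.210. Between colistin B and colistin they were -0.173, 0.118 and -0.192. Some same-numbered libraries may thus share a deviation. With the replicate block 1683 genes were called for colistin against control (1614 without) and 442 for sulbactam (402 without), and it changed no call of the 7 named genes. Of 945 values of the 7 named genes under alternatives, 903 stayed on their side of the threshold, called or not, 28 lost a call, 14 gained one and 0 changed direction as a call. The mean response over the 613 genes stayed between 1.23 and 1.28 for colistin, 0.789 and 0.874 for colistin B, and 1.57 and 1.68 for polymyxin B, while the small one for sulbactam ran from 0.00811 to 0.0424. Correlations between polymyxins changed little with the replicate block, without each control or among genes above the median expression (for colistin and colistin B, 0.862 to 0.914). The alternatives set out before the data were examined for rRNA and tRNA rows, pseudocounts and gene lists were not run, since no row could be told to be such an RNA, the unit was counts and no gene had a name. Genes changed less than 1.5-fold are the ones this depth and number of libraries miss most often.

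For each of the 10 pairwise comparisons, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split was the only 1 of 10 with as many calls as it gave (colistin 1614, colistin B 1311, polymyxin B 2069, sulbactam 402, the combination 2369 against control; the combination 1832 against colistin and 2205 against sulbactam; colistin B 1225 and polymyxin B 932 against colistin; polymyxin B 1572 against colistin B). The highest other was 1 for colistin, for sulbactam and for polymyxin B against colistin, and 0 for the rest.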

Other observations

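The runs of genes below were singled out after their values were seen, and the tests of a common response were chosen after the correlation they bear on. Genes with consecutive locus tags changed together. In the combination against control, 17 runs of at least 5 consecutive tags all changed at least 2-fold in 1 direction (9 up and 8 down) and held 125 of the 737 genes changed that much, where 1000 shuffles of the genes gave at most 2 such runs. Colistin gave 9 runs, colistin B 3, polymyxin B 13 and sulbactam 0 (14 genes changed at least 2-fold, so a run was hardly possible). The longest run of the combination, 18 tags from HPJ52_RS03815 to HPJ52_RS03900, was called higher throughout with colistin, colistin B, polymyxin B and the combination, while its log2 fold changes with sulbactam lay between -0.16 and 0.92. Its mean log2 level lay above control by 2.82 ± 0.0132 with colistin, 1.97 ± 0.104 with colistin B, 3.06 ± 0.0695 with polymyxin B and 2.69 ± 0.0534 with the combination (SD, n = 3), against 0.131 ± 0.0700 with sulbactam.

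Other runs differed between the combination and colistin. Some that rose with the combination stood above colistin. The median log2 difference was 1.04 for 7 tags from HPJ52_RS13800 to HPJ52_RS13830 and 1.31 for 5 from HPJ52_RS07740 to HPJ52_RS07760. The 5 tags from HPJ52_RS12130 to HPJ52_RS12150 also rose but stood below colistin (-0.46). The runs described next stood lower with the combination than with colistin. The 13 tags from HPJ52_RS18655 to HPJ52_RS18715 were cut as a run on the difference of differences, at least 2-fold below the sum. That they lay below colistin follows largely from this choice, since sulbactam alone moved them little. Colistin against control raised 10 of these tags in a row at least 2-fold, up to HPJ52_RS18700. All 13 genes rose with colistin and with colistin B and 12 with polymyxin B, and the combination was below colistin in all 13. The mean log2 level of the run was 1.19 ± 0.104 above control with colistin, 0.922 ± 0.129 with colistin B and 0.992 ± 0.0141 with polymyxin B, but -0.34 ± 0.0654 with the combination and -0.16 ± 0.202 with sulbactam (SD, n = 3). In 7 tags from HPJ52_RS17555 to HPJ52_RS17585, sulbactam stood at 0.591 ± 0.164 against control (3 of 7 genes called higher), colistin B at -1.09 ± 0.368, colistin at -1.99 ± 0.166, polymyxin B at -3.20 ± 0.407 and the combination at -3.88 ± 0.0757. All 7 genes were also called lower with polymyxin B than with colistin. The 11 tags from HPJ52_RS18270 to HPJ52_RS18320, which include HPJ52_RS18300 and HPJ52_RS18315, lay at -1.51 ± 0.425 with colistin B, -1.94 ± 0.154 with colistin, -2.19 ± 0.324 with polymyxin B and -3.78 ± 0.186 with the combination. Over all genes, 42 were higher than control with colistin and lower with the combination, and 22 the reverse. Of the 30 genes that sulbactam raised and colistin lowered, 21 were lower with the combination than with colistin.

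The log2 fold changes of the combination against control correlated between neighbouring tags at r = 0.465 over 3353 pairs, where shuffles reached 0.0524. Reads shared by overlapping or adjoining genes would confine this to immediate neighbours, but at 3 steps apart the correlation was still 0.207, above the 0.0511 that shuffles reached. Neighbours of like expression level do not account for it, since 0.462 remained after the trend of fold change on expression was removed. At 10 and 20 steps apart the correlation was 0.0694 and 0.0833, and the range of shuffles was not computed at these distances. A candidate explanation for the closer neighbours is that these tags are transcribed together in operons, which the data hold no annotation to test. Whether larger regions also moved together was not tested. As a hypothesis, each run may then be 1 response counted several times in the numbers of called genes.

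The correlation of the combination against colistin with polymyxin B against colistin B (r = 0.571) joins a drug pair to a difference between polymyxins. Its lowest value under RLE, upper-quartile and median-centred scaling was 0.570, but RLE shifts all genes of a comparison by nearly the same amount, so this decides nothing about the scaling. No single library carries it, since the lowest of 12 values with 1 library left out was 0.529. As a hypothesis, the combination and polymyxin B may both lie further along a common response than colistin and colistin B, whether by potency or by dose. Each difference was therefore set against a polymyxin response of other libraries. Polymyxin B against colistin B correlated with colistin against control at r = 0.605, but the combination against colistin correlated with colistin B against control at only 0.149, so the hypothesis stays open, and the labels give no dose to tell potency from dose.

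Genes of lower expression tended to stand higher with polymyxin B than with colistin, with a Spearman correlation across genes of -0.434 between the log2 fold change and the mean expression, and the other 10 comparisons ranged from -0.248 (the combination against colistin) to 0.0483 (colistin against control), all but the last below 0.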
